A study of Homo sapiens with 30 samples.

How the data were processed

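RNA from 30 pieces of human lung tissue was measured on 1-colour Affymetrix oligonucleotide arrays, 1 array per sample. An array of this kind holds probe sets, groups of short probes that match the 3' part of a transcript, and gives 1 value per probe set. The titles put 18 samples in a group lettered L and 12 in a group lettered N. The labels give no meaning for the letters, so the groups keep them here. The labels do not say whether the samples of a group came from separate donors, so the p-values measure the spread between samples.

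The deposited values are intensities on a linear scale, 1 per probe set and array, as the authors' value table gives them. The mean intensity of the deposited table without the lowest and highest 2% of probe sets was 100.03 on average, with a range of 100.025 to 100.037 over the 30 arrays, so every array had been scaled to a common level before deposit. The software that made the intensities, its version and the probe definitions are not given in the sources used here. Scanner files and detection calls were not used here, so a dim probe set cannot be told from background. Depth in reads has no counterpart on arrays, and the number of arrays limits the precision.

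The table holds 22283 probe sets, of which 68 are controls. The platform annotation gave 1 gene symbol for 19071 probe sets and several for 1043, and it did not list 2169. Of the probe sets with 1 symbol, 19059 were found by Entrez identifier in the reference gene table, and 0 symbols needed an update. Control probe sets and probe sets with several symbols or none were left out. For the 4310 genes with more than 1 usable probe set, the probe set with the highest mean over all 30 arrays was taken. Of the 11963 genes left, the dimmest 40% by mean over all arrays were removed, and 7178 genes were tested. No genome build is stated for the probe sets, so no coordinates are printed.

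Values were taken as log2(intensity + 16), with no further normalization between arrays. The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend in the variance and robust estimation. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Differences are L minus N. A fold is the difference on the log2(intensity + 16) scale turned back to a ratio, which understates the change of dim genes.

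Before the data were examined, 40 gene lists of lung cell types, matrix, protease, inflammatory, oxidant and stress genes and of other tissues that a piece of lung can hold were fixed, as were the main tests, the alternatives and the rule for named genes. Lists with at least 5 tested members, 36 in all, were tested with limma's camera with a preset correlation between genes of 0.01, with camera with an estimated correlation, and with fry. Each list mean per array was also compared by a 2-sided permutation test with 100000 resamples, which was added after the data were seen. Adjustment covered the 36 lists. The named genes were the 12 with the largest difference in each direction among those past the threshold, or up to 6 with the smallest p where fewer passed. In each list described, up to 4 members past the threshold were named. In a list with none, the 2 with the largest difference could be named, and some of these are left out below. XIST and genes of the Y chromosome were left out. Names outside this rule were chosen after their values were seen. They are the other genes past the threshold, further members of the lists that are said not to have passed, and other complement genes.

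Array measures were compared by 2-sided permutation tests with 100000 resamples: the median intensity, the spread of log2 values, the Spearman correlation of each array with the median array, and the log2 ratio of the 3' over the 5' control probe set of ACTB and of GAPDH, which rises as RNA degrades. The arrays were also searched for technical sets. The ratio of the 3' over the 5' probe set of BioC, a bacterial transcript added to each sample before hybridization, left a gap between 6 arrays (0.682 to 0.929) and the other 24 (0.341 to 0.580). The smaller set holds 4 L and 2 N arrays and the larger set 14 L and 10 N arrays. What sets them apart technically is not given in the sources used here. No pair of arrays held identical values, and the highest correlation between arrays was 0.911.

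The same code was tested on simulated data with the real means and spreads of the 7178 genes in the L against N comparison. It recovered 86% of genes with a true log2 difference of -1 and 92% at 1, but 22% at -0.5 and 30% at 0.5. Of 120 simulated calls, 4.17% were unchanged genes. The noise was drawn independently for each gene, so these rates need not hold where genes vary together. Alternatives covered quantile normalization, centring on the median, pseudocounts of 1 and 64, other filters, other ways to combine probe sets, variance models, array weights, RNA ratios as terms and a rank-sum test. After the data were seen, the array set, the spike-in level, arrays of low correlation, each single array and the mean of the group medians as reference for the array correlation were added. In 100 splits of the 30 arrays into 18 and 12, the real one included, the fits were repeated.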

Results

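Gene expression was measured in 30 pieces of lung tissue from smokers, 18 in group L and 12 in group N. As known of the study, it asked how transcripts differ between emphysematous lung removed at lung volume reduction surgery and lung resected from smokers with little or no emphysema. The labels do not state which letter stands for which tissue, so no disease status is given to either group here. Emphysema is the loss of alveolar walls and their elastic fibres, part of chronic obstructive pulmonary disease (COPD). Every array had been scaled to the same trimmed mean before deposit, and the median intensity over all probe sets was 53.1 ± 3.94 (SD, n = 30).

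Some transcripts of the extracellular matrix and of smooth muscle were higher in L than in N, with 4 of 23 tested collagen and matrix genes and 4 of 14 smooth muscle markers past the threshold. As groups, both lists passed a permutation test of their means but not camera with an estimated correlation (adjusted p = 0.0774 for both). LUM, which encodes lumican, a small proteoglycan that binds collagen fibrils, was 2.31-fold higher (log2 9.87 ± 0.56 in L, n = 18, against 8.66 ± 0.58 in N, n = 12, mean ± SD), and all 18 L arrays lay above the N mean. LOXL1, an enzyme that cross-links elastin, was higher by log2 1.39, or 0.85 to 1.88 with other pseudocounts since it was dim in N, also with 18 of 18 L arrays above the N mean. ACTA2, the actin of smooth muscle and myofibroblasts, was 1.87-fold higher, in 17 of 18 L arrays. S100A10, a calcium-binding protein family member that partners annexin A2, was 1.70-fold higher in N, with 18 of 18 L arrays below the N mean.

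In the limma comparison of 7178 genes, 35 passed an adjusted p of 0.05, of which 32 were higher and 3 lower in L. The count was 73 (72 higher, 1 lower) with each array centred on its median and 53 (41 higher, 12 lower) with the spike-in level as a covariate. Of the 35 genes, 33 stayed called with arrays centred on their median and 28 with the spike-in level. In the main fit the log2 differences of the 35 were between 0.46 and 1.39 in size. At an unadjusted p under 0.05, 858 genes differed, 578 higher and 280 lower in L. The median log2 difference of all genes tested was 0.04, and 0.11 with each array centred on its median, so the shift of a typical gene was small beside these differences. With quantile normalization limma called 26 genes, of which 23 were among the 35, and all 35 kept their direction. Leaving out single arrays moved the count by over 1.5 times: it was 21 without L10, 23 without L11, 20 without L12, 22 without L13, 19 without L15, 23 without L17, 21 without L18, 15 without N2 and 19 without N12. The genes that passed in all 30 such fits were LUM, LOXL1, IGFBP5, HP, C7, ACTA2, COL5A1, ISLR, C1R, FRZB, MXRA8, P4HB, PTGDS and S100A10, 14 of the 35.

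**Figure D1:**
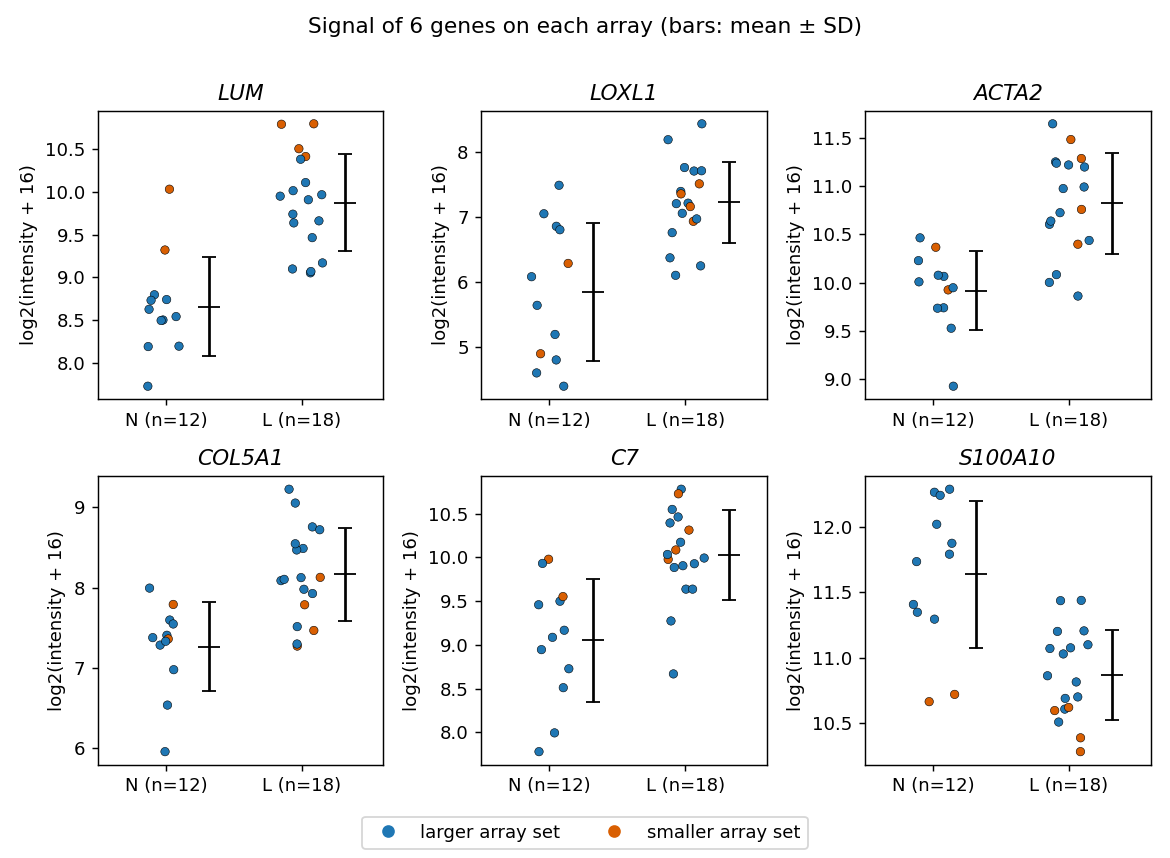
Signal of 6 genes on each array, as log2(intensity + 16), for the 12 N and 18 L arrays, with mean ± SD beside the points. Colours mark the larger (24 arrays) and the smaller (6 arrays) technical array set. All L arrays lie above the N mean for LUM, LOXL1 and COL5A1, 17 of 18 for ACTA2 and C7, and all lie below it for S100A10.

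LOXL1 differed by log2 1.39 ± 0.28 (SE, adjusted p = 0.0168). Its median intensity in N was 42.7, and its difference was 1.88 with a pseudocount of 1 and 0.85 with 64, below the 1.12 of LUM at that setting, so the order by size depends on the pseudocount. CHIT1, the chitinase of activated macrophages, followed at 1.38 ± 0.33 (adjusted p = 0.0434, 17 of 18 L arrays above the N mean), but its call was kept in only 10 of the 30 fits that left out 1 array and was lost with a pseudocount of 64 (adjusted p = 0.0809, in a range of 0.0177 to 0.733 over 17 alternatives). IGFBP5, a binding protein of insulin-like growth factors, was higher by 1.28 ± 0.25 (adjusted p = 0.0160), yet 3 of its 5 probe sets went the other way, and the mean over its probe sets was 0.27 (adjusted p = 0.429, in a range of 0.00486 to 0.967 over 19 alternatives). LUM had the smallest adjusted p, 0.00278, at 1.21 ± 0.20. HP, the haemoglobin-binding plasma protein haptoglobin, was higher by 1.07 ± 0.22 (adjusted p = 0.0168, 17 of 18). C7, a component of the membrane attack complex of complement, was higher by 0.97 ± 0.20 (adjusted p = 0.0194, 17 of 18).

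The next genes by size were MYLK, the kinase of the myosin light chain, at 1.91-fold, ACTA2 at 1.87-fold and COL5A1, a fibril-forming collagen chain, at 1.87-fold. DDIT4, an inhibitor of mTOR signalling induced by stress, was 1.85-fold higher, ISLR 1.85-fold and THBS2, a matricellular thrombospondin, 1.80-fold. Their adjusted p lay between 0.0130 (ACTA2) and 0.0434 (THBS2), and 16 to 18 of the 18 L arrays were above the N mean. The other 20 genes higher in L had log2 differences from 0.46 (TBC1D2B) to 0.83 (TAGLN). Among them were the complement proteases C1R (0.67 ± 0.14, adjusted p = 0.0168) and C1S (0.55 ± 0.12, adjusted p = 0.0241). P4HB, a subunit of the prolyl hydroxylase that modifies collagen, was higher by 0.73 ± 0.14 (adjusted p = 0.0130). FRZB, a secreted antagonist of Wnt, was higher by 0.76 ± 0.16 (adjusted p = 0.0168), and MGP, an inhibitor of calcification, by 0.57 ± 0.12 (adjusted p = 0.0241). For TPM2, MICAL2 and TBC1D2B, 1 of their 2, 3 and 3 probe sets went the other way.

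In the same comparison 3 genes were lower in L, a number that was 12 with the spike-in level as a covariate, 8 with quantile normalization and the array set as a term, and 1 with the RNA ratios as terms. S100A10 differed by -0.77 ± 0.16 (adjusted p = 0.0168, 18 of 18 L arrays below the N mean). VPS37B, part of the ESCRT-I sorting complex, differed by -0.77 ± 0.19 (adjusted p = 0.0446, 17 of 18), and PPP1R10, a regulatory subunit of protein phosphatase 1, by -0.49 ± 0.12 (adjusted p = 0.0434, 18 of 18). The calls of VPS37B and PPP1R10 were kept in 5 and 10 of the 30 fits without 1 array. S100A10 did not pass with the RNA ratios as terms, where its difference was -0.63 ± 0.16 (adjusted p = 0.0562, in a range of 0.000200 to 0.793 over 19 alternatives). LGALS14 (-0.73, adjusted p = 0.0585), FCGR1BP (-0.53, adjusted p = 0.0691) and SLC31A2 (-0.70, adjusted p = 0.0746) did not pass.

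The arrays fell into 2 technical sets, which the BioC spike-in ratio showed and which the first principal component (12.7% of the variance) separated as well. Between the sets, 1313 genes differed. Of the smaller set 4 of 6 arrays were L, and of the larger set 14 of 24 (Fisher's exact test, 2-sided, p = 1). With the set as a term, limma called 51 genes between L and N, 46 higher and 5 lower in L, and all 35 genes remained among them. Within the larger set alone (14 L, 10 N) it called 34 genes, 33 higher and 1 lower, of which 25 were among the 35. Within the smaller set (4 L, 2 N) limma called 0 genes, with 620 at an unadjusted p under 0.05, and 33 of the 35 kept their sign. CSRP1 (-0.04) and SERPINF1 (-0.05) did not. IGFBP5 (0.08) and S100A10 (-0.22, adjusted p = 0.793) kept their sign but little of their size, while LUM was at 0.95 and LOXL1 at 1.65. Over 19 alternatives COL5A1 had a lowest difference of 0.09 and a highest adjusted p of 0.955 in limma. The 6 arrays also helped to choose the 35 genes, so a kept sign says little.

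**Figure D2:**
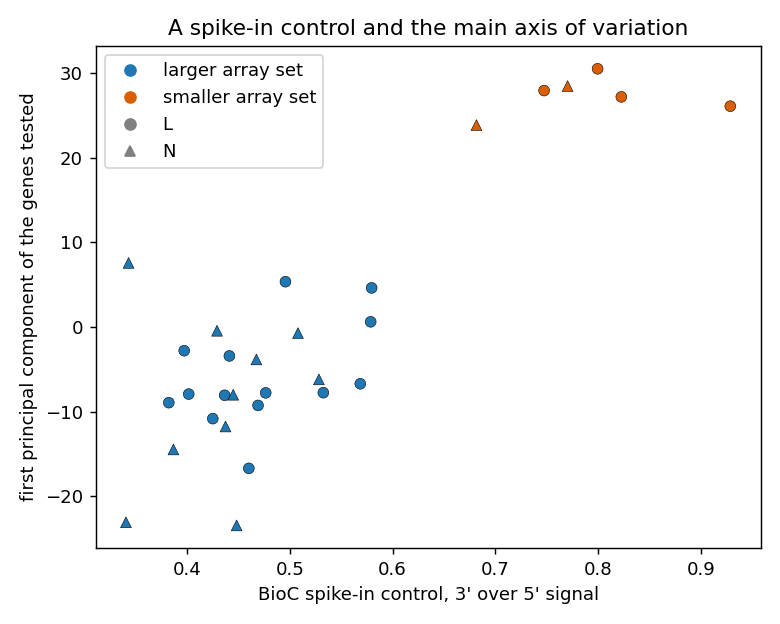
Ratio of the 3' over the 5' probe set of the BioC spike-in (x axis, no unit) against the first principal component of the 7178 genes (y axis, arbitrary unit), 1 point per array. The 6 arrays of the smaller set have ratios of 0.682 or more and components of 23.9 to 30.5, the other 24 have ratios up to 0.580 and components from -23.4 to 7.57, and both sets hold L (circles) and N (triangles).

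Collagens and matrix proteins were higher in L as a group by camera with the preset correlation (adjusted p = 1.11e-11), a call that was lost (adjusted p = 0.0774) with an estimated correlation. All 23 tested members had a positive difference, with a mean of 0.51 (95% CI 0.27 to 0.76), and 17 of 18 L arrays had a list mean above that of N. LUM, COL5A1, COL6A3 (0.66, adjusted p = 0.0434) and THBS2 rose, 19 members did not pass, and 11 passed when adjusted over the list alone. The fibrillar collagen COL1A1 (1.13, adjusted p = 0.144) and the proteoglycan BGN (0.94, adjusted p = 0.0611) were among those that did not pass. The permutation test of the list mean per array gave an adjusted p of 0.0045 and fry gave 0.00306.

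Smooth muscle markers were higher by a mean of 0.53 (95% CI 0.29 to 0.77), with 13 of 14 members positive and 18 of 18 L arrays above the N mean. Camera gave an adjusted p of 3.97e-10, or an adjusted p of 0.0774 with an estimated correlation, and the permutation test an adjusted p of 0.0045. ACTA2, MYLK, TAGLN (0.83, adjusted p = 0.0322) and TPM2 (0.81, adjusted p = 0.0237) rose, 10 did not pass, and 12 passed when adjusted over the list alone. MYH11, the myosin heavy chain of smooth muscle, had a difference of 0.42 (adjusted p = 0.316). Beside this, endothelial markers differed by -0.14 and ciliated cell markers by -0.02 in their list means, while secretory cell and gland markers differed by 0.24, fibroblast and pericyte markers by 0.23 and cartilage markers by 0.13.

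Elastic fibre genes were higher by a mean of 0.32 (95% CI 0.15 to 0.49), with 14 of 18 members positive and 16 of 18 L arrays above the N mean. Camera gave an adjusted p of 0.000911, or an adjusted p of 0.195 with an estimated correlation, and the permutation test an adjusted p of 0.00912. LOXL1 and MFAP4, a microfibril-associated protein (0.60, adjusted p = 0.0472), rose. The other 16 did not pass, and 6 passed when adjusted over the list alone. ELN, elastin itself, had a difference of 0.23 ± 0.26 (SE, adjusted p = 0.802), and FBN1, fibrillin-1, of 0.50 (adjusted p = 0.230). In the larger array set the means of the collagen, smooth muscle and elastic fibre lists were 0.57, 0.56 and 0.34. In the smaller set they were 0.31 (camera adjusted p = 0.0192), 0.37 (0.0113) and 0.21 (0.357), so the elastic fibre call was lost there.

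**Figure D3:**
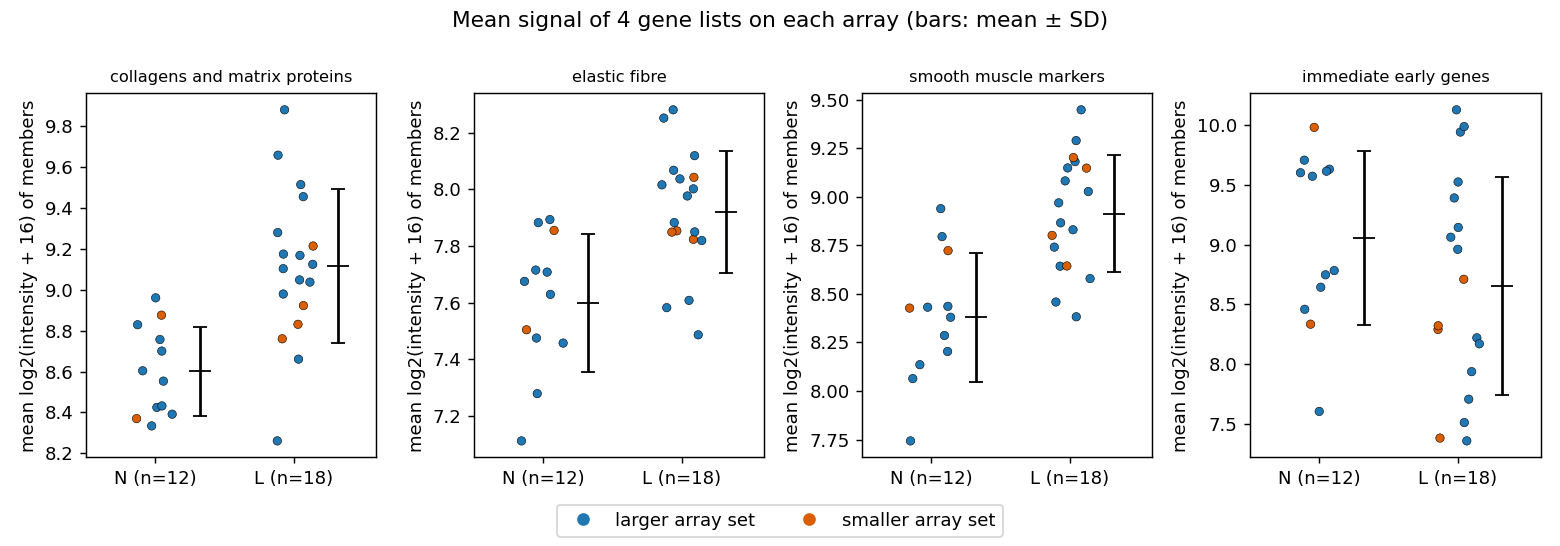
Mean log2(intensity + 16) of the members of 4 gene lists on each array, for 12 N and 18 L arrays, with mean ± SD beside the points and colours for the array set. The L mean lies above the N mean by 0.51 for collagens and matrix proteins, 0.32 for elastic fibre and 0.53 for smooth muscle markers, while immediate early genes spread widely in both groups (SD 0.91 in L and 0.73 in N).

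Camera with the preset correlation called 5 further lists, and none of these passed with an estimated correlation, fry or the permutation test. Fibroblast and pericyte markers had a mean of 0.23 (adjusted p = 0.0499, or an adjusted p of 0.369 with an estimated correlation). RGS5, a pericyte marker, rose (0.77, adjusted p = 0.0382), and the other 10 members did not pass. Immediate early genes, which are induced quickly by a stimulus, had a mean of -0.40 (95% CI -1.05 to 0.24), with 19 of 23 members negative and 0 past the threshold. FOSB differed by -1.55 (adjusted p = 0.409) and NR4A3 by -1.24 (adjusted p = 0.376). The list's adjusted p was 0.000114 with the preset correlation, and the adjusted p was 0.683 with an estimated correlation.

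Inflammatory cytokines and chemokines had a mean of -0.43, with 12 of 15 members negative and 0 past the threshold, and of -0.25 (adjusted p = 0.321) with the RNA ratios as terms, where the call was lost. CCL2, a chemokine for monocytes, differed by -1.21 (adjusted p = 0.412) and IL6 by -1.09 (adjusted p = 0.361). Endothelial cell markers had a mean of -0.14, with 11 of 20 negative, 0 past the threshold, HPGD at -0.75 and EMCN at -0.69 (adjusted p = 0.197 for both). Interferon response genes had a mean of -0.10, with 14 of 20 negative and 0 past the threshold. IFITM1 (0.40) and IRF7 (-0.37), the largest of them, went opposite ways. The preset adjusted p of these lists was 0.00562, 0.0343 and 0.0343, and the adjusted p with an estimated correlation was 0.485, 0.459 and 0.369. The interferon list had the opposite sign in the smaller array set (0.083). The immediate early mean was -0.25 in the larger array set and -0.98 in the smaller, and the inflammatory mean -0.31 (adjusted p = 0.0864, so the call was lost) and -0.86 (adjusted p = 0.0582).

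**Figure D4:**
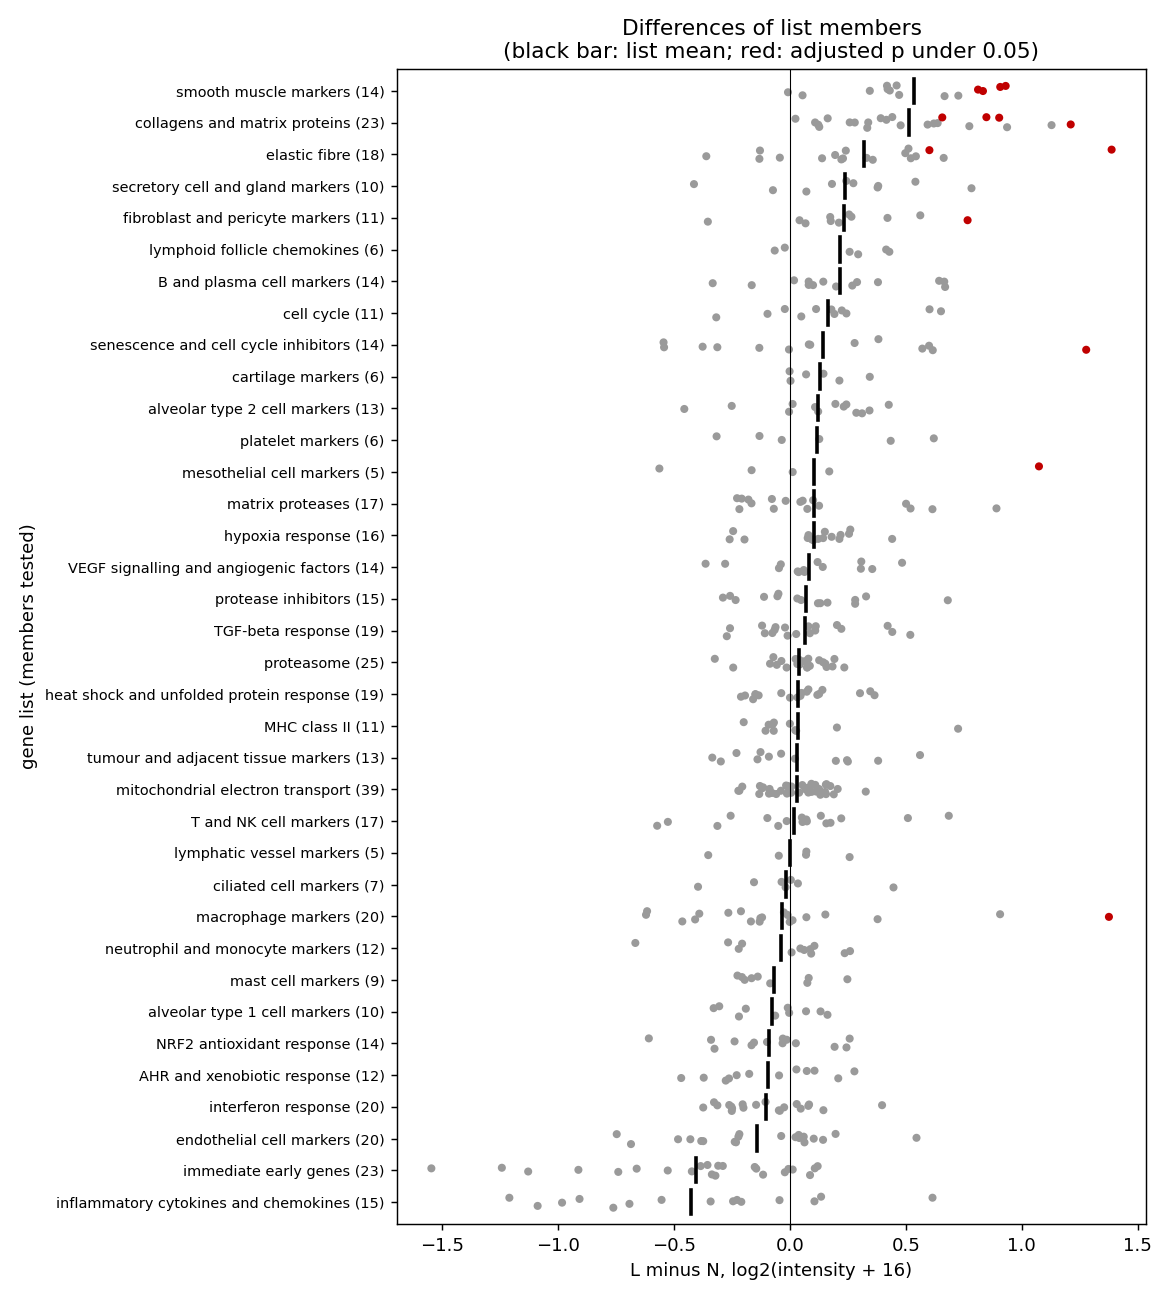
Difference L minus N in log2(intensity + 16) of every tested member (points) of the 36 gene lists tested, with the list mean as a black bar and genes past an adjusted p of 0.05 in red. The number of members tested stands in brackets. Smooth muscle markers (mean 0.53) and collagens and matrix proteins (0.51) lie highest, and inflammatory (-0.43) and immediate early genes (-0.40) lowest.

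The signs of RNA quality did not differ detectably between the groups, but with both ratios as terms limma called 29 genes, of which 17 were among the 35. The log2 ratio of the 3' over the 5' control probe set was 2.68 ± 0.85 in L and 2.63 ± 0.81 in N for ACTB (2-sided permutation test, p = 0.849) and 1.76 ± 0.87 and 2.03 ± 0.91 for GAPDH (p = 0.415, adjusted p = 0.519). Nor did the spread of log2 values (p = 0.339, adjusted p = 0.519). The median intensity over all probe sets was lower in L, 51.8 ± 3.96 against 55.2 ± 2.98 (p = 0.0164, adjusted p = 0.0410 over 5 array measures), but over the tested genes alone the difference was -0.70 (p = 0.593). L arrays correlated more closely with the median array than N arrays, with Spearman coefficients of 0.908 ± 0.016 and 0.859 ± 0.031 (SD, p = 1e-05, the smallest that the permutations can give, adjusted p = 5e-05). In the larger array set the difference in correlation was 0.0520 (p = 3e-05). With the mean of the group medians as the reference, so that the larger group weighed no more, it was 0.0427 (p = 4e-05). Without N8 and N10, the arrays with the lowest correlation with the others, limma called 23 genes, 19 higher and 4 lower in L, 18 of them among the 35, and camera with the preset correlation still called the collagen, smooth muscle and elastic fibre lists, none of which passed over all arrays with an estimated correlation (adjusted p = 0.0774, 0.0774 and 0.195).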

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

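The array set, spike-in level, low-correlation and single-array alternatives, the permutation of list means and the mean of the group medians as reference for the array correlation were chosen after the data were seen, and the others before. All 35 genes kept their direction with quantile normalization, where 23 of the 35 calls were kept, and with each pseudocount. Under other alternatives 3 genes and 1 list turned. TBC1D2B was at -0.16 without the probe sets whose suffix marks shared or mixed targets, CSRP1 at -0.036 and SERPINF1 at -0.053 in the smaller array set, and the interferon list at 0.083 there. The fibroblast and pericyte mean was -0.0068 in the smaller set, with camera's direction kept. The count of genes (35, with 32 higher and 3 lower in L) became 73 (72 and 1) with arrays centred on their median, 22 (20 higher) with no filter, 21 (19 higher) with no trend and no robust step, and 22 (20 higher) with array weights. It became 12 (11 and 1) with the mean of all probe sets and also 12 (11 and 1) without the shared-target probe sets, where 20 of the 35 genes could be tested. The rank-sum test called 7 (7 and 0). Without the low-correlation arrays it was 23 (19 higher), and with the spike-in level as a covariate 53, of which 12 were lower. Genes lower in L numbered 1 with RNA quality covariates and in the larger array set, 5 with the array set as a term and 8 with quantile normalization and the set. The smaller array set gave 0 (0 and 0), with 4 against 2 arrays. The cause of these moves was not tested, apart from the fewer genes or arrays in the fits that name them. Of the 8 lists, 0 (0 and 0) passed with an estimated correlation, 3 (0 lower) with fry and 3 (0 lower) by permutation of the array means. Lists numbered 5 (2 lower) with no filter, 4 (1 lower) without the shared-target probe sets and 4 (1 lower) in the smaller array set, and 2 were lower with RNA quality covariates. The collagen and smooth muscle lists passed under 20 of 21 alternatives and the elastic fibre list under 19, and all 3 without any single array. Apart from the estimated correlation, fry and the permutation, all these fits used camera with the preset correlation. That test called a median of 3 lists in the other splits of the arrays, so the tally says little about the test itself. Leaving out single arrays gave 15 to 48 genes (14 to 43 higher, 1 to 5 lower) and 4 to 10 lists (3 to 4 higher, 1 to 6 lower). The difference in median intensity was -0.70 over the tested genes alone (permutation test, p = 0.593). That set leaves out dim genes, probe sets with several symbols or none and further probe sets of a gene. Which of these moved the difference was not tested. Over the named genes and lists, the alternatives other than single arrays left 1631 gene values and 697 list values on their side of the threshold, while 249 and 45 lost a call and 16 and 2 gained one. The 1631 and 697 include genes and lists with no call in the main fit. These had no call to lose, and their direction was not compared. Among the 35 genes, calls were kept in from 3 of 17 alternatives (VPS37B) to 16 of 18 (LUM).

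The titles number the samples in both groups, and 12 numbers are shared. Same-numbered arrays did not deviate together: correlations were -0.18 to 0.12, 1 of 12 was over 0.1, and 0 of 12 L arrays correlated best with the N array of its number. The fit with the replicate block, over those 12 numbers, called 0 genes (0 higher, 0 lower) in limma, with 632 at an unadjusted p under 0.05, and 6 lists (3 higher, 3 lower). It rests on fewer arrays and spends terms on the numbers.

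Signal over background limits dim genes: no detection calls were used, and differences near the pseudocount are understated.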

Other observations

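The tests below of complement genes and of the array correlation were prompted by patterns seen in the results. Predictions for the matrix and smooth muscle pattern and for the array batch of immediate early genes were written after the results were seen. Predictions for the other explanations were written before their tests were run. Among lists that did not pass, several held single members with sizeable differences. Matrix proteases had a mean of 0.10, with MMP11, stromelysin-3, at 0.89 (adjusted p = 0.0915, 0.00733 when adjusted over the list alone, 1 of its 3 probe sets opposite) and MMP7 at 0.61 (adjusted p = 0.268). Of 17 members 0 passed over all genes and 2 over the list alone. Protease inhibitors had a mean of 0.07, with TIMP1 at 0.68 (adjusted p = 0.197). The TGF-beta response had a mean of 0.06, with CCN2 at 0.52 (adjusted p = 0.338). Macrophage markers had a mean of -0.03 although CHIT1 rose, and the other 19 members did not pass. Mesothelial markers (0.11) held HP, which rose, and the senescence list (0.14) held IGFBP5, which rose. Platelet markers (0.12) held SPARC at 0.62 (adjusted p = 0.0560), which is also a matrix gene. TREM1, a receptor of neutrophils and monocytes, was at -0.67 (adjusted p = 0.0797, 17 of 18 L arrays below the N mean) in a list with a mean of -0.04. FABP4, a fatty acid carrier of fat cells that is also found in alveolar macrophages and capillaries, was at -0.62 (adjusted p = 0.130). Cell cycle genes had a mean of 0.16, with MCM6 at 0.65 and MCM7 at 0.60 (adjusted p = 0.216 and 0.223, 0.0398 for both over the list alone).

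Markers of lung epithelium showed no list call. The mean was 0.12 for alveolar type 2 cells, with SFTPC at -0.46 (adjusted p = 0.329) and PGC at 0.43, -0.08 for alveolar type 1 cells, -0.02 for ciliated cells and 0.24 for secretory cells and glands, with BPIFA1 at 0.78 (adjusted p = 0.284). Oxidant and smoke response lists had means of -0.09 (NRF2) and -0.10 (AHR). In the NRF2 list GPX2 was at -0.61 (adjusted p = 0.291) and HMOX1 at -0.34 (adjusted p = 0.230). TIPARP of the AHR list was at -0.47 (adjusted p = 0.400). B and plasma cell markers had a mean of 0.22 and lymphoid follicle chemokines 0.22, with 12 of 14 and 4 of 6 members positive. Further means were 0.13 for cartilage, 0.10 for hypoxia, 0.08 for VEGF signalling, 0.04 for the proteasome and -0.07 for mast cells. Camera compares a list with the other genes tested, and the median difference of all genes tested was 0.04, so its direction is relative. In 7 lists the mean, the median and camera's direction differed in sign: neutrophils and monocytes (-0.04 and 0.05), MHC class II (0.03 and -0.07), T and NK cells (0.02 and 0.05), lymphatic vessels (-0.00085 and 0.07), tumour and adjacent tissue (0.03 and -0.04), mitochondrial electron transport (0.03 and 0.05) and heat shock and unfolded protein response (0.03 and 0.05), as mean and median, each below the other genes by camera. In the last of these the chaperone HSPA5 was at 0.35 (adjusted p = 0.148, 0.0427 over the list alone). Basal and squamous (0.10), erythroid (-0.16), adipocyte (-0.28) and neuroendocrine markers (0.01) had 4, 4, 4 and 2 tested members and were not tested.

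The members of the collagen, elastic fibre and smooth muscle lists were together higher in L by 0.45 ± 0.093 (SE) on the log2 scale. With the array set as a term the difference was 0.456 ± 0.095, and with both RNA ratios as terms 0.480 ± 0.10. These values argue against this array set or these ratios as the whole cause. Neither differed detectably between the groups, so the terms could move the difference little. A batch that goes with L and N could not be tested in this way. A lower share of 1 cell type in L should raise the markers of the others alike. Endothelial markers instead lay below smooth muscle markers by 0.675 ± 0.15. For a loss of endothelium or alveolar wall itself, the members of 7 immune and airway lists lay below smooth muscle markers by 0.490 ± 0.14. Smooth muscle was the list with the highest mean, so both gaps can be too wide, and the SE leaves this out. A joint loss of several cell types was not tested and stays open. More conducting airway in the L pieces stays open: ciliated markers (7 tested of 21 listed) lay below the 3 lists by 0.472 ± 0.16 and cartilage markers by 0.326 ± 0.14, but secretory cell and gland markers by only 0.219 ± 0.17. A larger share of vessel wall or scar, different sites of sampling, a change in the cells themselves and a difference in disease, which the labels do not assign, also stay open.

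Immediate early genes and inflammatory chemokines lay lower in L by camera's preset test only (adjusted p = 0.683 and 0.485 with an estimated correlation), and these genes can respond to surgery and handling. The immediate early mean differed by -0.404 ± 0.31 (SE), by -0.385 ± 0.32 with the array set as a term (-0.248 in the larger set, -0.983 in the smaller set of 4 L and 2 N arrays) and by -0.259 ± 0.34 with the RNA ratios as terms. Because the difference lies within 2 SE of 0 in each, array batch and RNA quality cannot be told apart from a difference between groups or from the spread between samples. Handling time was not analysed here and stays open.

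The N arrays correlated less with the median array than the L arrays, by 0.0489 ± 0.0086 (SE). With the array set and both RNA ratios as terms the difference was 0.0391 ± 0.0076, and with the level of the hybridization spike-ins as a term it was 0.0460 ± 0.0093. Both values argue against a linear effect of this array set, these ratios or this level as the whole cause. The set and the ratios did not differ detectably between the groups, so their terms could move the difference little. Within the groups the correlation changed by -0.0078 ± 0.0096 (SE) per log2 unit of spike-in level, which is within 2 SE of 0. Technical differences that go with L and N and that these terms do not measure could not be tested in this way. The spike-in level itself was 9.77 in L and 10.14 in N (log2, permutation test, p = 0.0390). Every array was scaled to a common level, so a higher spike-in level stands for a labelled sample that is dimmer relative to the controls, here in N. This holds if equal amounts of the controls were added. N tissue may be more varied for reasons that the labels do not give, and no biological explanation was tested.

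The splits argue against chance for the number of genes: the real split gave 35, and the highest of the other splits among 100 gave 2. So 1 of the 100, the real one, reached 35, the smallest share that 100 splits can give. The splits treat the samples as independent, which the labels do not state. Chance could not be excluded for the number of lists by the preset test: the real split gave 8, the other splits a median of 3 and at most 11, and 9 of the 100 gave at least 8.

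A hypothesis was that complement genes as a group are higher in L, since C1R, C1S and C7 were. Over 18 other complement genes the median difference was 0.10, 12 were positive and 0 passed, and camera gave p = 0.518 (p = 0.611 with an estimated correlation). C3 was at 0.45 (adjusted p = 0.150) and CD55 at -0.51 (adjusted p = 0.197). The test did not find the group shifted and does not exclude a small shift.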
